A study of Mus musculus with 60 samples.

How the data were processed

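The series holds 60 libraries of 3' end RNA sequencing (QuantSeq), a method that counts reads near the end of each transcript. Of these, 18 came from mouse embryonic fibroblasts (MEFs) of 9 embryos, and 42 from tissues of 9 mice which, per the labels, are of a line with a CD74-NRG1 fusion transgene and the Flp recombinase that switches it on. Groups were taken from the labels. The MEFs were negative, heterozygous or homozygous for the transgene, with 3 embryos each, and each embryo was sampled at passages 1 and 3. The tissue libraries were 30 normal tissues and 12 tumours. Per the labels, RNA was purified on columns, tissue was fresh frozen, and the libraries were read on a HiSeq 4000. The aligner, the counting program and the genome build are not given in the sources used here, so no coordinates are printed and the reference genome was not used.

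The deposited tables give expected counts per gene, in 1 table for MEFs and 1 for tissues, with the gene identifier and symbol on each line. Of all deposited values, those at 0 included, 6.6% in the MEF table and 8.35% in the tissue table were not whole numbers, so they are estimates that can divide reads between genes. The tests had been written for raw counts. The expected counts were therefore rounded to whole numbers first, which moved the total count by 0.0007% and 0.00054%. There are 46517 genes for MEFs and 54838 for tissues, of which 85 in the tissue table have no symbol. Tables of CPM, counts scaled to a common library total, were deposited for the same libraries and were not used here, because CPM was recomputed from the counts. All columns matched a sample by name, and 0 were left unmapped.

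Total counts per library were 3107529 to 5511781 for MEFs and 4837440 to 10089572 for tissues. A count of 0 allows up to 3 counts, which is 0.297 to 0.965 CPM in single libraries. Intervals and floors cover counting error only, since these reads carry no molecular identifiers in the sources used here. No pair of libraries of a group agreed within sampling noise. The smallest chi-square per degree of freedom between 2 libraries of a group was 2.99 in MEFs and 11.71 in tissues.

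The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, genes kept by filterByExpr at a minimum count of 10, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Standard errors of log2 fold changes were derived from the F statistic. Means and SDs of groups are TMM-scaled CPM within each comparison, while values of single libraries are plain CPM. The 18 MEF libraries entered 1 fit with 6 groups of genotype and passage. The tissue comparisons were fitted on the groups compared: sarcoma against muscle, liver tumour against normal liver, and sarcoma against liver tumour. A further fit held sarcoma and 4 normal tissues (muscle, liver, spleen and lung), and asked which genes were past the threshold and higher in sarcoma in all 4 contrasts. The 2 sarcoma libraries of mouse M00245 were summed, so the sarcoma group had 6 mice. The intestine tumour came from 1 mouse and got no test.

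A set of 38 gene lists of pathways and cell type markers was written down, 22 for MEFs, 26 for the sarcoma comparisons and 31 for the liver comparison. They were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. For each list the members past the threshold were counted over all genes tested and again adjusted over the list alone. Where the text gives no second count for a comparison of 2 groups, both counts were the same. The groups, tests, lists, main alternatives and the rule for naming genes were fixed before the data were examined. That rule names Cd74, Nrg1, Erbb2, Erbb3, Erbb4 and Egfr always. It adds the 8 highest and the 8 lowest log2 fold changes past the threshold, with at least 5 CPM in the higher group and no overlap between groups. Gene models without a proper name, antigen receptor segments and mitochondrial genes were passed over. It further adds up to 4 members of each list described, those with the smallest adjusted p, the 15 top genes of the 4-tissue comparison and the 10 top genes of the intestine tumour. Genes named for another reason are said to have been chosen after their values were seen, and some genes of both kinds are not reported here. Genes of families with near-identical copies (Mup, Krt, Sprr, Lce, Akr1c, Cyp, Serpinb3, H2 and others) can share reads, and their single values are uncertain.

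The alternatives were relative log expression scaling, DESeq2 1.42.0, no filter, a filter at a mean of 5 CPM, leaving out each embryo or library, only the groups compared, a covariate of Y-linked expression, the embryo or mouse as a block, other treatments of the M00245 sarcomas, removal of haemoglobin, immunoglobulin and mitochondrial genes, and camera with an estimated correlation or with the block. Others were added after the data were seen: library size alone, without embryos 1 and 3, without the later library of embryo 8, with or within a possible batch (mice M00235 to M00238 against M00245 to M00249, whose column names number tissues differently), and without mouse M00246 or M00247. The later library of embryo 8 is passage 3 by its description and group tag, passage 1 by its title, and passage 5 by its column name. It was used as passage 3. The liver library of mouse M00249 is a tumour by its group tag, although its title omits this.

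Libraries of the same embryo or mouse are paired by the labels. Correlations of their deviations from the group means were 0.054 to 0.337 over the 9 embryo pairs (6 above 0.1) and -0.075 to 0.331 over 4 pairs of sarcoma and muscle. They were -0.15 and -0.137 for 2 pairs of liver tumour and normal liver, and -0.09 and 0.002 for 2 pairs of sarcoma and liver tumour.

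Simulated counts with gene means and library sizes of the data and 100 changed genes per fold tested the steps, not power in the data. For homozygous against negative MEFs at passage 1 (12051 genes), 68% of 2-fold and 94% of 4-fold changes were recovered, with 8 false calls. For sarcoma against muscle (14697 genes) the shares were 37% and 86%, with 4 false calls. For the livers (13256 genes) they were 12% and 75%, with 3 false calls, and no changed gene was called in the wrong direction. Preparation and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.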

Results

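CD74-NRG1 is a gene fusion that joins the transmembrane protein Cd74 to neuregulin 1 (Nrg1), a ligand of the receptor Erbb3. Gene expression was measured in 60 libraries from a mouse line made to carry the fusion behind a stop cassette in the Rosa26 locus. The fibroblast part held 18 libraries from 9 embryos, with 3 embryos negative, 3 heterozygous and 3 homozygous for the transgene, each at passages 1 and 3. The tissue part held 8 normal livers, 7 normal lungs, 6 spleens, 6 muscles, 2 brains and 1 kidney, beside 7 sarcoma libraries from 6 mice, 3 liver tumours and 2 libraries of an intestine tumour. Total counts per library lay between 3107529 and 5511781 in fibroblasts and between 4837440 and 10089572 in tissues. Mitochondrial transcripts took 0.42 to 0.79% of fibroblast counts, 9.79 to 20.06% in normal liver, 11.1 to 21.0% in liver tumours, 5.56 to 13.4% in sarcomas and 21.09 to 34.8% in muscle.

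The fibroblast comparisons asked what the transgene changes in cultured cells. Nrg1 (ENSMUSG00000062991), the ligand part of the fusion, was read first, as a check of the genotype labels. Whether reads of the transgene are counted under the mouse gene is not stated in the sources used here. In the 3 embryos labelled heterozygous, Nrg1 lay between 32.3 and 57.2 CPM at passage 1 and between 59.8 and 75.1 at passage 3. Embryos 7 and 10, labelled homozygous, gave 141 and 84.9 CPM at passage 1 and 158 and 117 at passage 3. Embryos 5 and 8, labelled negative, gave 1.57 and 0.485 CPM at passage 1 and 0.8 and 1.09 at passage 3. The 2 remaining embryos went against their labels. The libraries labelled negative from embryo 1 held 132 and 147 CPM, from 549 and 666 counts. The libraries labelled homozygous from embryo 3 held 0.644 and 1.28 CPM, from 2 and 5 counts. All groups below follow the labels, so every direction between genotypes rests on these groups as labelled.

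**Figure D1:**
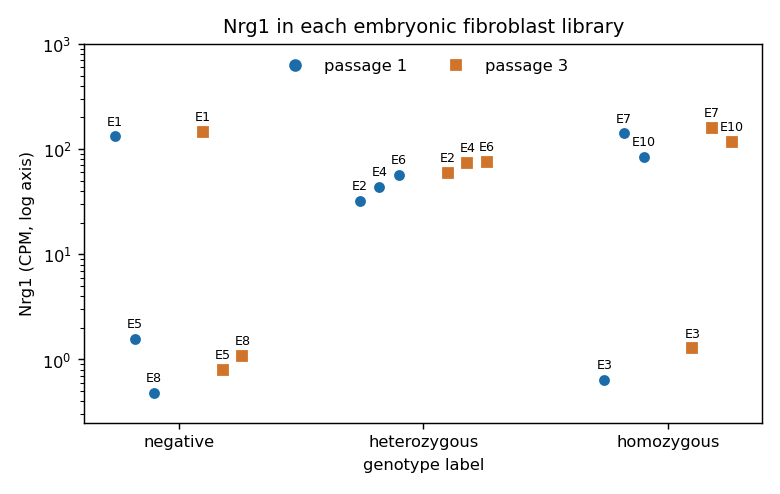
Nrg1 in CPM (log axis) in each fibroblast library by labelled genotype, with passage 1 as blue circles and passage 3 as orange squares, each labelled with its embryo. Embryo 1, labelled negative, lies at 132 and 147 CPM, and embryo 3, labelled homozygous, at 0.644 and 1.28 CPM.

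With the labels as given, Nrg1 did not differ between genotypes. The log2 fold change of homozygous against negative was 0.77 (SE 1.55, adjusted p = 0.88, n = 3 and 3) at passage 1 and 0.93 (SE 1.54, adjusted p = 1.0) at passage 3. Heterozygous against negative gave 0.03 and 0.54, with adjusted p of 1.0 and 0.99, and homozygous against heterozygous gave 0.74 and 0.39, with adjusted p of 0.91 and 1.0. Without embryos 1 and 3, chosen after their values were seen, the log2 fold change for Nrg1, homozygous vs negative, passage 1, was 6.74 (adjusted p = 4.6e-05). For Nrg1, homozygous vs negative, passage 3, it was 7.09 (adjusted p = 1.8e-05). For Nrg1, heterozygous vs negative, passage 1, it was 5.44 (adjusted p = 0.0005), and for Nrg1, heterozygous vs negative, passage 3, it was 6.13 (adjusted p = 7.5e-05). For Nrg1, homozygous vs heterozygous, passage 1 and Nrg1, homozygous vs heterozygous, passage 3 it was 1.31 and 0.97, with adjusted p of 0.67 and 1.0. The receptor Erbb2 differed by log2 fold changes between -0.01 and 0.09 over the 6 comparisons (SE 0.21 to 0.22). Egfr gave 0.43 (SE 0.2, adjusted p = 0.45) for homozygous against negative at passage 1 and 0.39 (adjusted p = 0.59) against heterozygous, and -0.16 to 0.09 in the other 4 comparisons. Erbb3 at 0 to 5.13 CPM, Erbb4 at 0 to 0.363 CPM and Cd74 at 0 to 1.71 CPM were too low in fibroblasts to test.

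At passage 1, camera called macrophage and interferon-stimulated genes lower and p53 targets higher in embryos labelled homozygous than in embryos labelled negative, and each of these calls was lost with an estimated correlation between genes. Levels were uneven within the homozygous label, as embryo 7 lay among the negative embryos for macrophage and interferon-stimulated genes. The macrophage genes had a median log2 fold change of -1.33 over 12 measured members (camera, adjusted p = 1.2e-07; adjusted p = 0.36 with an estimated correlation). Among them, Csf1r, the receptor for colony-stimulating factor 1, was at 42.9 ± 26.4 CPM against 77.0 ± 13.7 (SD, n = 3 and 3; log2 fold change -0.83, SE 0.36). The lysosomal protein Cd68 was at 5.45 against 16.2 CPM (log2 -1.48), and Mpeg1 and the mannose receptor Mrc1 gave -1.26 and -1.49. The interferon-stimulated genes had a median of -1.31 over 13 members (adjusted p = 9.2e-07; adjusted p = 0.36 with an estimated correlation). Of these, Bst2 (tetherin) was at 91.4 ± 117 against 241 ± 38.4 CPM, and the sensor Ifih1 and the antiviral genes Oas1a and Rsad2 gave log2 fold changes of -1.37, -1.47 and -1.31. The 13 measured p53 target genes had a median of 0.54 (adjusted p = 1.7e-05; adjusted p = 0.36 with an estimated correlation). Pmaip1, which encodes the cell death factor Noxa, was at 40.2 ± 40.7 against 8.14 ± 2.18 CPM (log2 2.3, SE 0.62, adjusted p = 0.29). Ccng1 was at 184 ± 92.9 against 106 ± 13.5 CPM (log2 0.8, SE 0.27, adjusted p = 0.34), and Eda2r and Zmat3 gave 1.19 and 0.54. No member of these 3 lists was past the threshold over all genes tested. Adjusted over the list alone, 4 of the p53 targets rose and none of the other 2 lists did.

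The same lists differed between single embryos. At passage 1, the mean log2(CPM + 1) of the macrophage genes was 1.54 in embryo 10 and 1.6 in embryo 3, both labelled homozygous, and 2.23 in embryo 2, labelled heterozygous. It was 4.62 to 5.26 in the other 6 embryos, embryo 7 among them. The interferon-stimulated genes were at 1.32, 1.85 and 2.09 in embryos 10, 3 and 2 and at 4.71 to 5.37 in the others. The p53 targets stood at 6.77 in embryo 10, 6.09 in embryo 3 and 5.46 to 5.97 in the others. The myogenic precursor genes stood at 3.35 in embryo 10, 1.62 in embryo 3, 1.6 in embryo 2 and 0.735 to 1.07 in the others. At passage 3 the macrophage genes of the 9 embryos lay between 3.96 and 4.9.

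Of the other lists of this comparison, DNA replication genes were lower (16 members, median -0.24, adjusted p = 0.00014; adjusted p = 0.36 with an estimated correlation), as were collagen and matrix genes (18, -0.29, adjusted p = 0.0015; adjusted p = 0.36 with an estimated correlation) and fibroblast genes (12, -0.31, adjusted p = 0.0057; adjusted p = 0.39 with an estimated correlation). Contractile genes were higher (12, 0.42, adjusted p = 0.0011), and so were the 3 measured endothelial genes (0.57, adjusted p = 0.044), both with adjusted p = 0.36 with an estimated correlation. Adjusted over the list alone, the endothelial genes Kdr (log2 0.97) and Eng (0.57) rose, as did Phlda1 (0.69) of the ERK-responsive genes, Myog (7.2) and Chrna1 (2.11) of the myogenic precursor genes, and 1 gene of the Schwann cell list. The Myog mean was 52.6 ± 84.7 CPM against 0.326 ± 0.128, an SD above the mean. The other 14 lists had no camera call. They were ErbB receptors and ligands (5 members, adjusted p = 0.35), ERK-responsive genes (18, 0.077), myogenic precursor (3, 0.069), FOXO targets (10, 0.94), mitosis (17, 0.24), senescence and secreted factors (12, 0.51) and matrix-degrading proteases (12, 0.58). The rest were glycolysis and hypoxia (14, 0.94), cholesterol synthesis (17, 0.55), epithelium (6, 0.58), Schwann cell and glia (5, 0.53), neuron (2, 0.39), adipocyte (1, 0.84) and sex-linked genes (5, 0.55). For FOXO targets the median was 0.07 and the mean -0.08, with the test pointing up. For proteases the median was -0.01 and the mean 0.09, and for glycolysis the median was -0.01 and the mean 0.08.

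None of the 12051 genes tested was past the threshold of edgeR between homozygous and negative embryos at passage 1, where the smallest adjusted p was 0.17. At an unadjusted p below 0.05 there were 1315, and DESeq2 called 9 (Amd2, E2f1, Lce1h, Pck2, Ptgs2, Ssh1, Tmcc3, Tnnc1 and Tspan6, chosen after their values were seen). The count depended on 1 embryo, since without embryo 7, labelled homozygous, edgeR called 890 genes, 336 higher and 554 lower. The groups of 1590 genes did not overlap, where chance gives 10% of genes for 3 against 3.

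The other genotype comparisons gave the same count of 0 with edgeR. Heterozygous against negative at passage 1 had 316 genes at an unadjusted p below 0.05 and 0 by DESeq2. Macrophage genes (median -0.43, adjusted p = 5.6e-05), interferon-stimulated genes (-0.42, adjusted p = 8.4e-05) and collagen and matrix genes (-0.16, adjusted p = 0.02) were lower, each with adjusted p = 0.74 with an estimated correlation. Homozygous against heterozygous at passage 1 had 1022 at an unadjusted p below 0.05 and 1 by DESeq2, Amd2. There the p53 targets were higher (median 0.56, adjusted p = 0.00021; 7 of 13 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). DNA replication (-0.25, 0.00024), macrophage (-0.81, 0.00076) and interferon-stimulated genes (-0.74, 0.003) were lower, all 3 with adjusted p = 0.58 with an estimated correlation. Without embryo 7 this comparison called 147 genes, 54 higher and 93 lower. At passage 3, homozygous against negative had 451 genes at an unadjusted p below 0.05 and 0 by DESeq2, with no list called (smallest adjusted p 0.2). Heterozygous against negative had 529, with 1 by DESeq2 and no list called (smallest adjusted p 0.088). Homozygous against heterozygous at passage 3 had 417, with 1 by DESeq2. In it mitosis genes were higher (median 0.2, adjusted p = 0.00046; adjusted p = 0.75 with an estimated correlation). Epithelial genes were lower (-0.95, adjusted p = 0.0021; adjusted p = 0.068 with an estimated correlation), as were glycolysis genes (-0.1, adjusted p = 0.019; adjusted p = 0.75 with an estimated correlation). Amd2 was chosen after its values were seen. Adjusted over the list alone, 1 myogenic gene rose in homozygous against heterozygous at passage 1 and 1 collagen and matrix gene at passage 3, and no other member of an uncalled list passed in these comparisons. At passage 3 the tests of some uncalled lists differed in sign from their medians. For homozygous against negative these were myogenic precursor (median 0.36, mean 0.34, test down), neuron (0.66, 0.66, down) and proteases (0.06, -0.04, down). For heterozygous against negative they were myogenic precursor (-0.1, -0.4, up), neuron (0.25, 0.25, down) and sex-linked genes (0.05, -0.04, down), and for homozygous against heterozygous neuron (0.41, 0.41, down). Medians and means also differed in sign for cholesterol synthesis in the comparison of homozygous with negative (-0.02, 0.05) and for fibroblast genes in that of heterozygous with negative (-0.06, 0.01). The same was true of myogenic precursor (-0.19, 0.74) and Schwann cell genes (-0.03, 0.14) in that of homozygous with heterozygous. At passage 1 FOXO targets (-0.1, -0.01, up) and Schwann cell genes (0.02, -0.07, up) did so in homozygous against heterozygous. Whether the homozygous effect differed between passages was tested as an interaction, with 0 genes by edgeR, 514 at an unadjusted p below 0.05 and 0 by DESeq2. Of its uncalled lists 1 FOXO target fell adjusted over the list alone, and ERK-responsive genes had a median of 0.01 and a mean of -0.04.

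Passages were compared over all genotypes, to show what time in culture changes. Between passages 1 and 3, with 9 embryos at each, Eln, which encodes the elastic fibre protein elastin, fell by 2.18 on the log2 scale (SE 0.28, adjusted p = 0.0031), from 103 ± 38.2 to 23.0 ± 13.6 CPM. Tnmd, the tendon gene tenomodulin, fell from 56.0 ± 20.6 to 21.6 ± 9.45 CPM (log2 -1.42, SE 0.21, adjusted p = 0.0041). Lmnb1, which encodes lamin B1 of the nuclear envelope, fell from 316 ± 27.7 to 231 ± 19.5 CPM (log2 -0.45, SE 0.06, adjusted p = 0.0031). Aebp1, a collagen-binding protein of the matrix, rose from 90.5 ± 22.7 to 171 ± 22.7 CPM (log2 0.92, SE 0.13, adjusted p = 0.0041). H2-DMb1, a chaperone subunit for loading MHC class II, rose from 2.86 ± 1.25 to 8.0 ± 1.91 CPM (log2 1.5, SE 0.22, adjusted p = 0.0041). Also higher at passage 3 were Pcdhb17 (log2 1.0), Ephx1 (0.9), which encodes microsomal epoxide hydrolase, Lrrc32 (0.72), the growth factor Fgf2 (0.66), Hsd17b7 (0.63) of cholesterol synthesis and Map1a (0.59). Lower were Gucd1 (-0.54), Fam178a (-0.39), Ppid (-0.31), the nuclear exporter Xpo1 (-0.26) and the co-chaperone Stip1 (-0.18). Each of these genes moved in its direction in 9 of 9 embryos, which adds no evidence. The naming rule admits only genes without overlap between the passages, so this was fixed by the choice of genes. Nrg1 (log2 0.33, adjusted p = 0.9), Erbb2 (-0.19, adjusted p = 0.48) and Egfr (0.35, adjusted p = 0.11) were not past the threshold.

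Of 14 glycolysis and hypoxia genes, 7 rose (8 adjusted over the list alone; camera, adjusted p = 3.3e-06; adjusted p = 0.22 with an estimated correlation). They were Vegfa (log2 0.47, from 75.8 ± 6.88 to 105 ± 9.12 CPM), the mitophagy factor Bnip3 (0.85), Pdk1 (0.71), Ndrg1 (0.79), the glucose transporter Slc2a1 (0.33), Pkm (0.26) and Ldha (0.23). Of 17 cholesterol synthesis genes none was past the threshold (4 rose adjusted over the list alone), with Cyp51 at 0.39 (adjusted p = 0.051), Fdft1 at 0.41, Hmgcs1 at 0.3 and Mvd at 0.43 (list adjusted p = 3.4e-06; adjusted p = 0.39 with an estimated correlation). Mitosis genes were lower (17 members, 1 fell, 3 adjusted over the list alone; adjusted p = 3.8e-05; adjusted p = 0.39 with an estimated correlation), with Top2a at -0.26 and Cenpf at -0.24 (adjusted p = 0.088). DNA replication genes were lower (16 members, 1 fell, 2 adjusted over the list alone; adjusted p = 5.9e-05; adjusted p = 0.39 with an estimated correlation), with Mcm2 at -0.29. Senescence and secreted factors were higher (12 members, 0 past the threshold, 4 adjusted over the list alone; adjusted p = 0.0031; adjusted p = 0.39 with an estimated correlation), with Mmp3 at 1.24, Igfbp3 at 0.83 and Cdkn2a at 0.44. Collagen and matrix genes were higher as a list (18 members; adjusted p = 0.0093; adjusted p = 0.39 with an estimated correlation), although Eln fell, and Bgn (0.25) was the only member that rose (4 rose and 1 fell adjusted over the list alone). Of 12 contractile genes, Actg2 (-0.85) and Myh11 (-0.99) fell, also adjusted over the list alone (adjusted p = 0.0024; adjusted p = 0.39 with an estimated correlation). Macrophage (12 members, adjusted p = 0.015; adjusted p = 0.62 with an estimated correlation) and interferon-stimulated genes (13 members, adjusted p = 0.032; adjusted p = 0.65 with an estimated correlation) were called higher with no member past the threshold, beside the low passage 1 levels of embryos 2, 3 and 10.

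The remaining lists were not called between passages. In 2 of them single genes fell, Etv4 (-0.41) of the 18 ERK-responsive genes (1 rose and 3 fell adjusted over the list alone; adjusted p = 0.2) and Col15a1 (-1.36) of the 12 fibroblast genes (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.2). No member passed in ErbB receptors and ligands (adjusted p = 0.87; 1 rose adjusted over the list alone), FOXO targets (0.5), p53 targets (0.95), matrix-degrading proteases (0.2), myogenic precursor (0.19), endothelium (0.41; 1 fell alone), epithelium (0.7; 1 rose and 1 fell alone), Schwann cell and glia (0.7; 1 fell alone), neuron (0.41), adipocyte (0.95) or sex-linked genes (0.97). The median and mean differed in sign for FOXO targets (-0.01 and 0.08), p53 targets (0.02 and -0.07) and Schwann cell genes (0.03 and -0.04). For sex-linked genes the median (0.18) and mean (0.04) were above 0 while the test pointed down. In all, edgeR called 340 of 12051 genes, 218 higher and 122 lower at passage 3, with 45 and 28 of them by 2-fold or more.

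The passage count moved with single embryos. It ranged from 24 without embryo 8 to 779 without embryo 10, with 39, 51, 34, 124, 186 and 108 without embryos 1 to 6 in turn. It was 142 without the later library of embryo 8, whose labels give different passages, and 4 without embryos 1 and 3. Those 4 genes were Eln, Fam162a, Grem1 and Spp1, chosen after their values were seen. Of the 24 genes of the naming rule past the threshold, Eln alone kept its call under every alternative tried. With the embryo as a block, 3 of the others, Myh11, Stip1 and Top2a, lost it, and with library size as the only scaling Top2a lost it (-0.26, adjusted p = 0.061) and Cyp51 gained it (0.4, adjusted p = 0.042).

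Sarcomas were compared with muscle, the mesenchymal normal tissue sampled. Erbb3 (ENSMUSG00000018166), the receptor for Nrg1, rose from 23.0 ± 2.22 CPM in muscle to 189 ± 36.9 in sarcoma (log2 3.03, SE 0.16, adjusted p = 8.2e-09, n = 6 and 6). Sox10, a transcription factor of the Schwann cell lineage, rose from 9.25 ± 2.71 to 470 ± 99.8 CPM (log2 5.67, SE 0.24, adjusted p = 3e-09). Sparc, a matrix protein, rose from 252 ± 47.8 to 4311 ± 957 CPM (log2 4.09, SE 0.23). The fast myosin Myh4 fell from 11210 ± 3571 to 39.2 ± 41.0 CPM (log2 -8.16, SE 0.78), and the keratin Krt13 from 23230 ± 6094 to 25.9 ± 11.9 CPM (log2 -9.8, SE 0.46, adjusted p = 4.6e-09). Cd74, the invariant chain of MHC class II, rose from 32.1 ± 9.03 to 72.3 ± 31.8 CPM (log2 1.17, SE 0.29, adjusted p = 0.0029), and the receptor Erbb4 fell (log2 -4.36, SE 0.63, adjusted p = 3.8e-05). Nrg1 (-0.38, SE 0.51, adjusted p = 0.54), Erbb2 (0.14, SE 0.16, adjusted p = 0.45) and Egfr (-0.27, SE 0.19, adjusted p = 0.22) were not past the threshold. With library size as the only scaling these 3 moved to 0.63 (adjusted p = 0.28), 1.09 (adjusted p = 0.00016) and 0.67 (adjusted p = 0.0091), so Nrg1 and Egfr changed sign. Nrg1 also changed sign in the second batch alone (0.07), and Erbb2 in the first (-0.12). In the muscle of M00246 Nrg1 was at 1.3 CPM, against 26.4 to 38.5 in the other muscles, and without this mouse the log2 fold change for Nrg1, sarcoma vs muscle, was -0.65 (adjusted p = 0.077).

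The genes with the largest rises were mostly at 0 in muscle. Over the floor of 3 counts for the group, Rlbp1 was at least 96.2-fold higher in sarcoma, Pnlip (pancreatic lipase) at least 78.8-fold, the neuronal gene Plppr1 at least 66.4-fold, Hoxb8 at least 65.6-fold and Il1rapl1 at least 61.6-fold. Car6, a secreted carbonic anhydrase, had 2 counts in muscle and a ratio of 418 (95% counting interval 116 to 3460). Gpr17, a receptor of immature oligodendrocytes, was at 49.6 ± 46.7 CPM (log2 8.15, SE 0.78), and the metalloprotease Adam12 at 41.6 ± 15.6 CPM (log2 8.14, SE 0.53). Among the largest falls, Lrrc14b was at least 605-fold lower and Ces1h had a ratio of 1890 (522 to 15600) on 2 counts in sarcoma. The other 6 were genes of stratified epithelium and hair or their families: Serpinb3c (-10.03), Krt4 (-10.02, from 9364 ± 1982 to 8.92 ± 6.07 CPM), Defb4 (-9.92), Krtap13 (-9.85), Krt76 (-9.83) and Krt13.

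Genes of 7 lists were higher in sarcoma by camera. Of 10 Schwann cell and glia genes 8 rose (8 adjusted over the list alone; adjusted p = 9.5e-05; adjusted p = 0.088 with an estimated correlation). Among these were the adhesion molecule Ncam1 (log2 5.01, 20.3 ± 2.85 to 654 ± 92.3 CPM), Sox10, the cadherin Cdh19 (5.04), the neurotrophin receptor Ngfr (3.27), S100b (4.7), the neural crest factor Foxd3 (5.78) and Gap43 (2.07). Of the others 1 fell, and the myelin gene Mbp gave -0.14 (adjusted p = 0.75). Of 18 collagen and matrix genes 17 rose, also adjusted over the list alone (adjusted p = 9.4e-09; adjusted p = 0.4 with an estimated correlation), among them Postn (5.3), Col5a1 (3.92) and Col5a2 (4.18). Of 10 matrix-degrading proteases 9 rose, also adjusted over the list alone (adjusted p = 0.0014; adjusted p = 0.4 with an estimated correlation), including Mmp14 (3.32), cathepsin K (Ctsk, 3.17), Adamts4 (4.66) and Adamts5 (2.85). Of 17 ERK-responsive genes 12 rose, with the feedback inhibitors Spred1 (2.1), Dusp6 (2.56) and Spry2 (1.93) and the factor Etv1 (4.12) among them. Dusp5 fell (-1.38), and 2 fell adjusted over the list alone (adjusted p = 0.006; adjusted p = 0.5 with an estimated correlation).

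All 17 mitosis genes rose, also adjusted over the list alone (adjusted p = 7.3e-05; adjusted p = 0.51 with an estimated correlation), with Mki67 at 2.29, Top2a at 2.34, Cenpf at 2.32 and Birc5 at 2.3. Of 16 DNA replication genes 14 rose (adjusted p = 0.0071; adjusted p = 0.57 with an estimated correlation). Of 13 macrophage genes 11 rose (adjusted p = 0.0075; adjusted p = 0.57 with an estimated correlation), among them Mpeg1 (2.35), Adgre1 (1.9), Fcgr1 (2.98) and the complement gene C1qb (1.61).

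Lower lists included the contractile apparatus of the fibre. Of 14 skeletal muscle fibre genes 13 fell (adjusted p = 5.4e-05; adjusted p = 0.5 with an estimated correlation), with myoglobin (Mb) at -6.57, nebulin (Neb) at -4.59 and the calcium pump Atp2a1 at -5.92. The exception was Myh2 (-0.14, adjusted p = 0.89). Of 7 myogenic precursor genes 5 fell, or 6 adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.5 with an estimated correlation). Of 11 contractile and smooth muscle genes 8 fell (adjusted p = 0.01; adjusted p = 0.57 with an estimated correlation). All 16 oxidative phosphorylation genes fell (adjusted p = 1.5e-10; adjusted p = 0.4 with an estimated correlation), with Uqcrc2 at -2.83, Cox5a at -3.62, Atp5b at -2.87 and Uqcrfs1 at -3.02. Of 15 glycolysis and hypoxia genes 11 fell (adjusted p = 7.3e-05; adjusted p = 0.4 with an estimated correlation). All 8 epithelial genes fell (adjusted p = 0.0025; adjusted p = 0.5 with an estimated correlation), including Spint1 (-3.89), Cldn4 (-3.81) and the splicing factors Esrp2 (-2.98) and Esrp1 (-3.23). All 5 erythroid genes fell (adjusted p = 0.0071; adjusted p = 0.5 with an estimated correlation). Of 9 endothelial genes 7 fell, Kdr (-1.74) and Vwf (-1.73) among them, while Eng (0.78) rose (adjusted p = 0.039; adjusted p = 0.57 with an estimated correlation).

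The muscle libraries held transcripts of stratified epithelium at high levels. Krt13 ranged from 10800 to 26190 CPM over the 6 muscle libraries and was the 8th most abundant transcript of the group, beside Myh4 at 5364 to 10110 CPM. Krt4 ranged from 4755 to 9403 CPM and loricrin (Lor) from 1702 to 4400. Krt13 was at 12.3 to 116 CPM in other tissue libraries. Falls or flat values against muscle, also of ErbB genes, may reflect this epithelium.

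**Figure D2:**
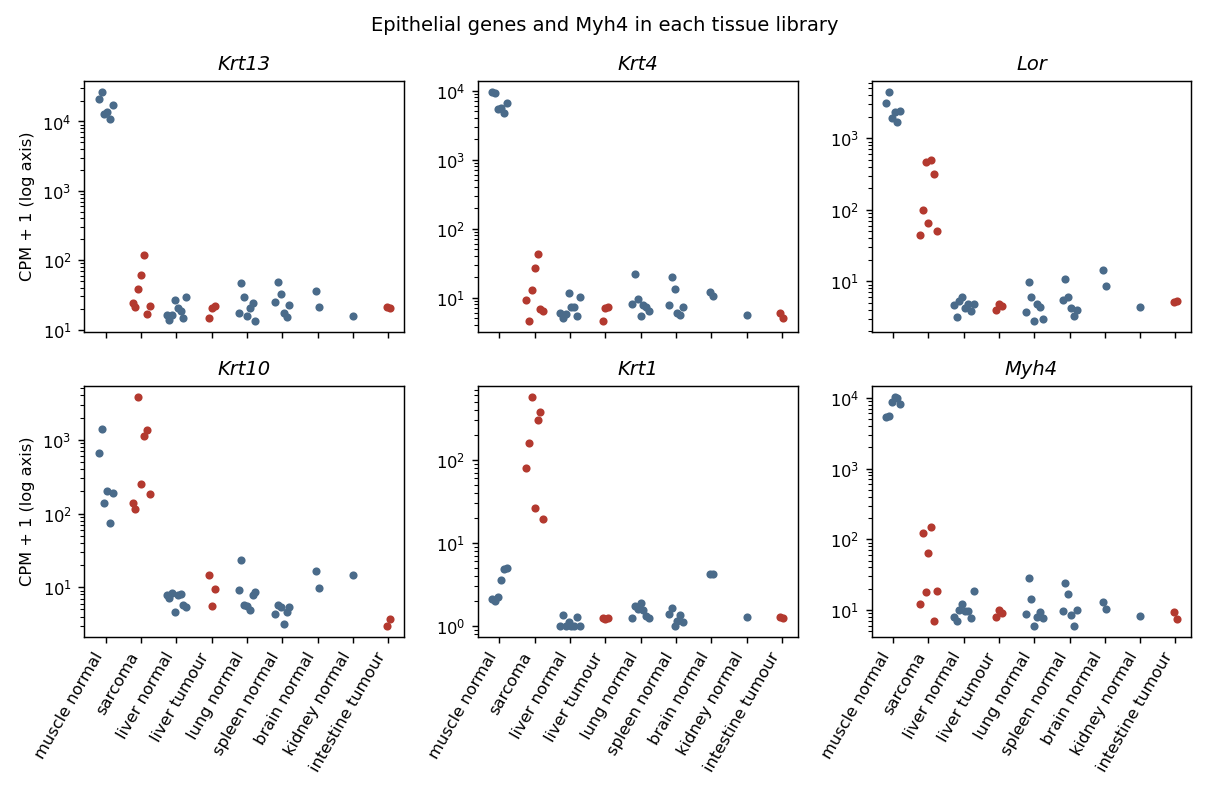
CPM + 1 (log axis) of Krt13, Krt4, Lor, Krt10, Krt1 and Myh4 in each tissue library by group, with normal tissues in blue and tumours in red. Krt13 lies between 10800 and 26190 CPM in the 6 muscle libraries and between 12.3 and 116 CPM in all others.

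Other lists had no camera call between sarcoma and muscle. Of 10 ErbB receptors and ligands, Erbb3 and the ligand Hbegf (1.72) rose, while Tgfa (-3.34), Egf (-2.54), Ereg (-3.72), Btc (-2.65) and Erbb4 fell (adjusted p = 0.35). Of 11 FOXO targets only Fbxo32, an atrophy gene of muscle, fell (-3.53; adjusted p = 0.54). Of 11 p53 targets Bax (1.39) rose and Ccng1 (-2.54), Cdkn1a (-2.51), Phlda3 (-0.94) and Aen (-0.69) fell. This list had a median of 0.22, a mean of -0.37 and a test pointing down (adjusted p = 0.43). Of 12 interferon-stimulated genes 5 rose (4 adjusted over the list alone; adjusted p = 0.089), including Ifit3 (1.42), Bst2 (1.45), Ifit1 (1.57) and Oasl2 (0.92). Of 8 Wnt genes Axin2 (1.33) and Tcf7 (1.32) rose and Ascl2 (-2.87), Lef1 (-1.62), Rnf43 (-2.27) and Znrf3 (-0.74) fell (adjusted p = 0.44). Of 7 MHC class II genes 6 rose (adjusted p = 0.09). Of 12 fibroblast genes 6 rose, Col15a1 (5.01), Pdgfrb (1.73), Fap (1.82) and Thy1 (1.73) among them, and Dpt (-1.71) fell (adjusted p = 0.09). The adipocyte genes Plin1 (3.39) and Adipoq (3.06) rose (4 measured, 3 adjusted over the list alone; adjusted p = 0.51). Of 3 B and plasma cell genes Cr2 (2.54) rose and Sdc1 (-1.55) fell (adjusted p = 0.91). Cd5, the only T and NK cell gene measured, fell (-5.01; adjusted p = 0.13), and none of 3 neutrophil genes passed (adjusted p = 0.57). With library size alone the list medians of FOXO targets (-0.13 to 0.82) and Wnt genes (-0.56 to 0.41) changed sign.

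In all, 9541 of 14697 genes were past the threshold, 4933 higher and 4608 lower in sarcoma, with 3220 and 3103 by 2-fold or more. DESeq2 called 11752. The share of higher calls was 51.7% with TMM scaling and 82% with library size alone (9252 higher, 2029 lower), as the median log2 fold change of all genes moved from 0.064 to 1.03. All fold changes above are relative to the TMM reference. The first batch of mice gave 7430 calls (3682 higher, 3748 lower) and the second 8153 (4037 higher, 4116 lower), with 9319 with the batch as a term. The 55 genes of the naming rule past the threshold kept their calls under every alternative that gave them a value, which the stricter filter did not for Erbb4 and Fcgr1, nor the T1 library of M00245 alone for Rlbp1.

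To leave out genes that only mark muscle, sarcoma was set against muscle, liver, spleen and lung together (6 against 27 libraries), and the smallest of the 4 fold changes was taken. Col20a1, a fibril-associated collagen, was at 325 ± 106 CPM in sarcoma against 1.31 ± 0.726 over the normal tissues (smallest log2 7.15, SE 0.33, adjusted p = 3e-17). Ajap1, an adherens junction protein, was at 463 ± 182 against 2.1 ± 1.39 CPM (7.19, SE 0.38, adjusted p = 4e-15). Erbb3 was higher in sarcoma than in each of the 4 tissues (2.09, SE 0.21, adjusted p = 9.4e-11), at 175 ± 34.7 against 20.2 ± 16.0 CPM. Gpr17 had the largest smallest fold (8.12, SE 0.75). The others by rank were Krt77 (7.67), Slitrk3 (7.58), Krt2 (7.31), Flg2 (7.3), Cdh10 (7.26), Rasgef1c (7.26), Car6 (6.83), Clca3a2 (6.81), Hoxb9 (6.79), Ndst3 (6.7), Kcnh8 (6.63) and Alox12e (6.59). Erbb2 gave 0.12 (SE 0.34, adjusted p = 0.79), which became 1.09 (adjusted p = 0.0089) with library size alone. Cd74 (-3.44), Nrg1 (-1.4), Erbb4 (-4.37) and Egfr (-3.95) had smallest folds below 0, so they were not higher than in all 4.

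Several of these genes belong to epidermis and varied between sarcomas. Krt2, a keratin of the upper epidermis, ranged from 0.174 to 1146 CPM over the sarcoma libraries, Krt10 from 116 to 3757 and Krt1 from 18.4 to 565. The ranges of glial genes were narrower, with Sox10 at 414 to 902 CPM, Foxd3 at 112 to 361, Col20a1 at 202 to 692, Ngfr at 64.7 to 107, Gpr17 at 26.2 to 212 and Erbb3 at 152 to 434. The plot of glial genes by tissue shows these per library.

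**Figure D3:**
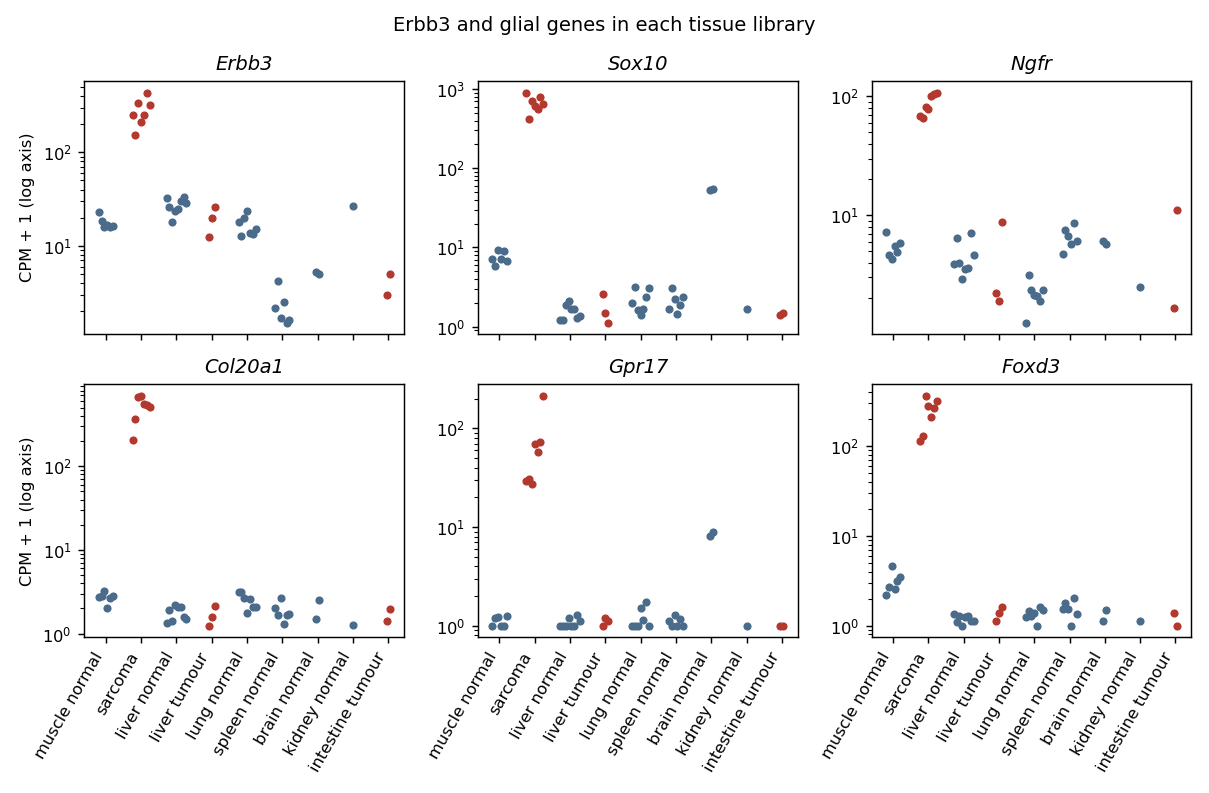
CPM + 1 (log axis) of Erbb3, Sox10, Ngfr, Col20a1, Gpr17 and Foxd3 in each tissue library by group, with normal tissues in blue and tumours in red. The 7 sarcoma libraries lie at 414 to 902 CPM for Sox10 and at 152 to 434 CPM for Erbb3.

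Of 10 Schwann cell and glia genes 7 were higher in sarcoma than in all 4 tissues, also adjusted over the list alone, with Sox10 at 5.65, Foxd3 at 5.76 and Cdh19 at 5.01. So were 14 of 18 collagen and matrix genes (14 adjusted over the list alone), with Col1a2 at 4.06, Col5a1 at 3.29, Col1a1 at 5.11 and Col3a1 at 4.72. The same held for 7 of 12 matrix-degrading proteases (7 adjusted over the list alone), including Mmp14 (2.9), Adamts5 (2.8), Mmp2 (1.99) and Ctsk (2.06). Of 17 ERK-responsive genes 6 passed (6 adjusted over the list alone), including Etv1 (3.27), Dusp4 (2.21), Spred1 (1.43) and Spry2 (1.0). Of 12 fibroblast genes 4 passed, Col15a1 (4.99), Fap (1.8), Thy1 (1.71) and Pdgfrb (0.8), and of 13 ErbB receptors and ligands only Erbb3. None of 17 mitosis genes was higher than in all 4 tissues. Lower in all 4 comparisons were 5 of 10 erythroid and 4 of 10 endothelial genes, and 1 gene each of the contractile, oxidative phosphorylation, Wnt and B cell lists. No member of any other list passed in either direction, and camera was not run on this comparison. The count was 1174 of 17766 genes higher in all 4 contrasts, 829 of them by 2-fold or more, and 498 lower in all 4. DESeq2 called 1421 higher. The share of higher genes was 70.2% with TMM scaling and 95.7% with library size alone (2114 higher, 94 lower). The 32 genes of the naming rule past the threshold kept their calls under every alternative that gave them a value, but the low-count filter left Krt2 out in 13 others.

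Liver tumours of 3 mice were compared with normal livers of 8. The fetal liver gene Afp rose from 1.02 ± 0.413 CPM in normal liver to 119 ± 184 in tumours (log2 6.84, SE 0.8, adjusted p = 0.00041). Ubd, a ubiquitin-like modifier, rose from 0.966 ± 0.673 to 186 ± 74.8 CPM (log2 7.55, SE 0.42, adjusted p = 2.1e-06). The keratin Krt8 rose from 120 ± 14.9 to 692 ± 369 CPM (log2 2.53, SE 0.26, adjusted p = 0.00013). Pck1, the first enzyme of gluconeogenesis, fell from 1817 ± 570 to 285 ± 80.5 CPM (log2 -2.67, SE 0.37, adjusted p = 0.00098). Cd74 (ENSMUSG00000024610) rose from 27.5 ± 15.6 to 136 ± 110 CPM (log2 2.31, SE 0.49, adjusted p = 0.011), and Egfr fell from 295 ± 124 to 90.8 ± 4.21 CPM (log2 -1.7, SE 0.38, adjusted p = 0.014). Erbb3 (-0.69, SE 0.24, adjusted p = 0.084), Nrg1 (0.27, adjusted p = 0.85) and Erbb4 (-1.77, adjusted p = 0.32) were not past the threshold, and Erbb2 was too low to test.

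The largest rises were Apela, a hormone of early development (log2 10.35, 124 ± 135 CPM against 0.0776), Slc7a11, the cystine transporter (9.09), Akr1c18 (8.93), Tekt5 (7.86), Ubd and Anxa13 (7.39). Eps8l3 was at least 313-fold and Meltf at least 176-fold higher, since all normal livers were at 0. The largest falls were major urinary protein genes, secreted pheromone carriers of the mouse liver. Mup8 was at least 175-fold lower, Mup17 (-8.06), Mup9 (-7.67), Mup12 (-6.86), Mup6 (-6.39) and Mup18 (-5.42) fell, and Mup22 fell from 9336 ± 4101 to 238.2 ± 180 CPM (-5.29, SE 0.79). The sulfotransferase gene Sult2a7 (-6.57) fell as well. Mup genes are nearly identical copies, so their single values are uncertain.

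**Figure D4:**
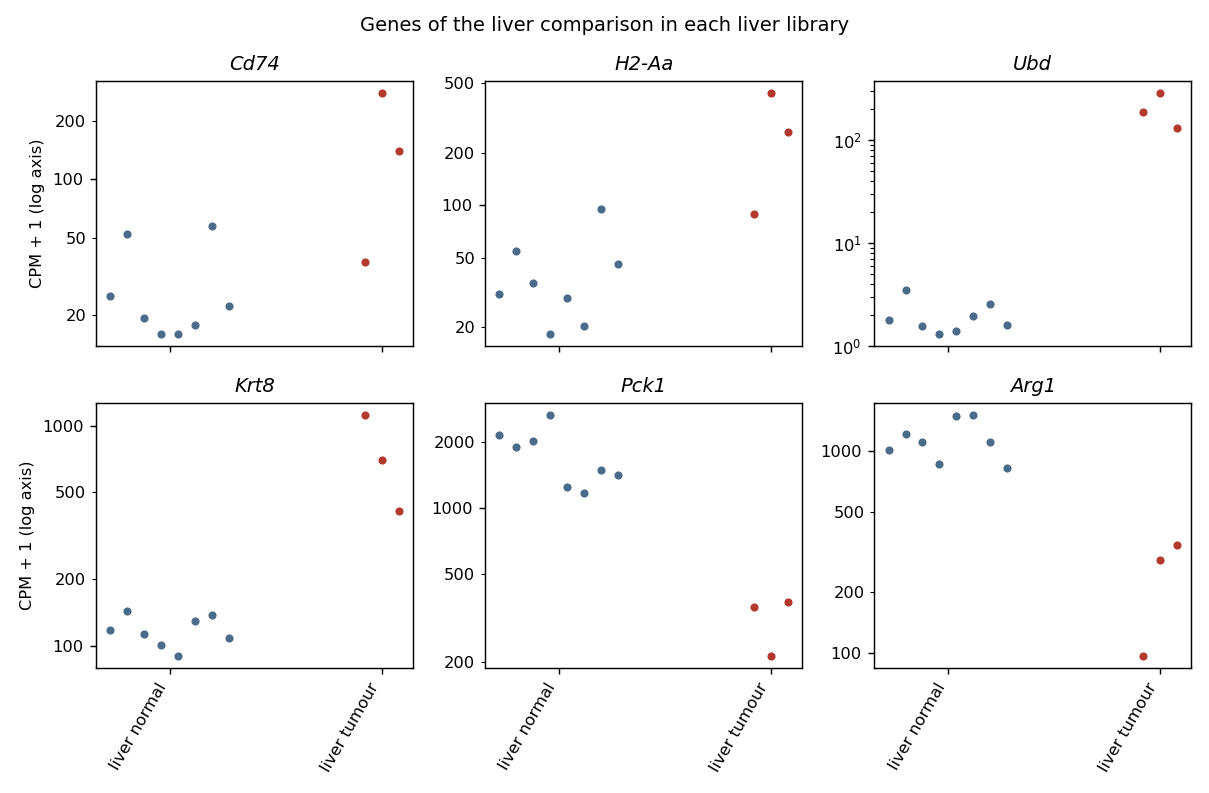
CPM + 1 (log axis) of Cd74, H2-Aa, Ubd, Krt8, Pck1 and Arg1 in each of 8 normal livers (blue) and 3 liver tumours (red). Ubd lies between 0.306 and 2.48 CPM in normal livers and between 131 and 288 CPM in tumours.

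Lists higher in the tumours included genes of the fetal or transformed liver. Of 8 oncofetal genes 7 rose, also adjusted over the list alone (adjusted p = 2.7e-05; adjusted p = 0.2 with an estimated correlation), with Scd2 (4.09), Tspan8 (7.27), Ly6d (6.77), the imprinted RNA H19 (8.3), Gpc3 (4.95) and Spp1 (3.32) beside Afp. Of 7 MHC class II genes 6 rose (7 adjusted over the list alone; adjusted p = 2.6e-05), including H2-Aa (2.53), H2-Eb1 (2.47) and H2-Ab1 (2.28). Of 9 matrix-degrading proteases 5 rose, Mmp12 (4.25), Plat (5.41) and Plau (1.66) among them (adjusted p = 0.00019; adjusted p = 0.12 with an estimated correlation). Mmp13 had 2 counts in normal liver and a ratio of 155 (42 to 1290). Of 17 collagen and matrix genes 7 rose (12 adjusted over the list alone; adjusted p = 2.6e-06), including Sparc (1.94), Fbn1 (2.18), Col3a1 (2.21) and Col1a2 (1.88). Of 17 mitosis genes Cdc20 (2.77), Cdk1 (2.25) and Aurka (1.66) rose (4 adjusted over the list alone; adjusted p = 9.1e-10). The normal liver of M00247 went the other way, with a mean log2(CPM + 1) of the list of 3.48, against 2.88 to 3.8 in the tumours and 0.779 to 1.75 in the other normal livers, and with Mki67 at 41.9 CPM, above every tumour (at most 18.9). Of 15 ERK-responsive genes 5 rose (7 adjusted over the list alone; adjusted p = 0.0039), including Ier3 (3.72), Dusp5 (3.87), Egr1 (3.72) and Dusp6 (1.8). Of 7 epithelial genes 5 rose (adjusted p = 0.019), with Krt18 (2.12), Krt5 (3.23) and Cldn3 (0.94) beside Krt8. Of 14 interferon-stimulated genes Cxcl10 (3.45) and Isg15 (1.81) rose (adjusted p = 0.00038). For all of these lists but the oncofetal and protease genes adjusted p was 0.29 with an estimated correlation.

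Of 12 p53 targets Cdkn1a (3.23), Phlda3 (2.56) and Gdf15 (1.87) rose (adjusted p = 0.02; adjusted p = 0.32 with an estimated correlation). Of 14 glycolysis and hypoxia genes Ndrg1 (2.82), Slc2a1 (1.23) and Egln3 (1.14) rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.02; adjusted p = 0.29 with an estimated correlation). Tpm1 (1.55) of 10 contractile genes rose (2 adjusted over the list alone; adjusted p = 0.023), and so did Cd3d (2.64) of 4 T and NK cell genes (2 adjusted over the list alone; adjusted p = 0.011), both with adjusted p = 0.29 with an estimated correlation. Lower were the urea cycle and gluconeogenesis genes (6 of 10 fell, 8 adjusted over the list alone; adjusted p = 9.1e-10; adjusted p = 0.12 with an estimated correlation). Among them were Arg1 (-2.43), Ass1 (-2.36) and Asl (-2.07) of the urea cycle. Of 12 cytochrome P450 and bile acid genes 4 fell, the bile acid importer Slc10a1 (-3.76), Cyp8b1 (-4.03), Cyp2c29 (-3.18) and Cyp27a1 (-1.65), and Cyp3a11 was at 2.38 (adjusted p = 0.14). Adjusted over the list alone 1 rose and 6 fell (adjusted p = 1.8e-07; adjusted p = 0.29 with an estimated correlation). Of 14 hepatocyte genes Serpina3k (-2.7) fell and albumin (Alb) was at 0.07 (adjusted p = 0.95), with the list called lower (adjusted p = 0.011; adjusted p = 0.29 with an estimated correlation). Wnt genes were called lower (8 members, 0 past the threshold, adjusted p = 0.033; adjusted p = 0.5 with an estimated correlation), although their median (0.21) and mean (0.2) were above 0. Oxidative phosphorylation genes, with 0 of 16 past the threshold, were called lower just under the threshold (adjusted p = 0.05 after rounding; adjusted p = 0.72 with an estimated correlation).

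No camera call was made for ErbB receptors and ligands (Btc 3.46 and Tgfa 1.55 rose and Egfr fell, of 8; 3 rose and 2 fell adjusted over the list alone; adjusted p = 0.89) or FOXO targets (Ccng2 1.45 rose and Klf15 -1.35 fell, of 10; adjusted p = 0.49). The same was true of cholesterol synthesis (Cyp51 1.22 and Hmgcs1 1.5 rose, of 17; adjusted p = 0.28), fibroblast (Prrx1 3.18 and Col15a1 1.54 rose, of 8; adjusted p = 0.17) and endothelium (Emcn 1.86 rose, of 9; adjusted p = 0.39). In the cholangiocyte list Sox9 (2.36) rose and Onecut1 (-1.74) fell, of 4 measured (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.69). Neb (-1.57) fell in the muscle fibre list (adjusted p = 0.073) and Klf1 (-1.93) in the erythroid list. The erythroid median was 0.31 and mean 0.05, with the test pointing down (adjusted p = 0.89). No member passed in DNA replication (adjusted p = 0.1), macrophage (0.57), neutrophil (0.89), B and plasma cell (0.69), intestinal epithelium (0.24) or Schwann cell genes (0.93). The neutrophil median of -3.94 stood beside S100a8 at 1584 CPM in the normal liver of M00247, against 1.86 to 10.9 in the other normal livers. With library size alone the FOXO median changed sign, from -0.05 to 0.14.

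In all, 1406 of 13256 genes were past the threshold, 925 higher and 481 lower in tumours, with 773 and 362 by 2-fold or more, and DESeq2 called 1987. The share of higher calls was 65.8% with TMM scaling and 80.6% with library size alone (1375 higher, 331 lower), with the median of all genes moving from 0.086 to 0.263. The count was 860 without the tumour of M00248, which ended 13 of the 54 calls among genes of the naming rule, among them Cd74, H2-Ab1, Cxcl10, Dusp5, Dusp6, Egr1, Krt5 and Mup8. Cd74 was at 277 CPM in that tumour, 139 in that of M00249 and 36.4 in that of M00236, against 14.9 to 56.7 in normal livers. Afp was at 364, 17.9 and 11.4 CPM in the same order. With the mouse as a block 0 genes were past the threshold of edgeR, with 904 at an unadjusted p below 0.05, and DESeq2 was not run with the block. Only 2 mice gave both tissues, too few to decide. The first batch held 1 tumour, that of M00236, against 4 normal livers, and gave 2289 calls (1114 higher, 1175 lower) with that tumour assumed to vary like the livers. The second, with 2 tumours and 4 normal livers, gave 164 (128 higher, 36 lower), and the batch as a term 1189. Nrg1, liver tumour vs normal liver, gave -0.32 for the tumour of M00236 in the first batch. In the normal liver of M00246 Nrg1 was at 0.675 CPM, against 27.6 to 83.3 in the others, and without this mouse it gave 0.02 (adjusted p = 0.98).

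The kinds of tumour were compared with each other, 6 sarcomas against 3 liver tumours. Erbb3 was higher in sarcoma (212 ± 42.8 against 28.6 ± 9.61 CPM; log2 2.89, SE 0.32, adjusted p = 2.7e-05), and so was Erbb2 (22.0 ± 4.55 against 0.761 CPM; log2 4.88, SE 0.71, adjusted p = 0.00019). Egfr (-2.15, SE 0.27, adjusted p = 6.4e-05), Nrg1 (30.8 ± 15.7 against 91.7 ± 18.7 CPM; -1.57, SE 0.38, adjusted p = 0.0048) and Cd74 (80.8 ± 35.2 against 233 ± 187 CPM; -1.53, SE 0.52, adjusted p = 0.026) were lower. With library size alone Nrg1 (-0.59, adjusted p = 0.24) and Cd74 (-0.56, adjusted p = 0.38) lost their calls, and Cd74 also lost its call without the liver tumour of M00248, with the block, and with only the sarcoma library T1 of M00245. Genes at 0 in liver tumours included Clca3a2 (44.4 ± 30.4 CPM in sarcoma), Lce1m (at least 241-fold higher), the phagocytic receptor Megf10 (234), the glutamate receptor Grik2 (174), Hoxb9 (143) and Crispld1 (142). The ratio was 2570 (461 to 102000) for Sprr2a2 and 2590 (465 to 102000) for Krt2, each with 1 count in liver tumours. The call of Krt2 was lost without any 1 of the 3 liver tumours. Genes at 0 in sarcoma included Cideb (at least 5880-fold lower), the hormone Fgf21 (538) and Gimd1 (517). Gstm3 (-11.18), Igfbp1 (-10.78), Cyp3a11 (-10.69), Akr1c20 (-10.54) and H2-Q1 (-10.54) were the other large falls.

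All 10 Schwann cell genes were higher in sarcoma (adjusted p = 1.4e-05; adjusted p = 0.06 with an estimated correlation), with Sox10 at 8.82, Foxd3 at 8.27 and S100b at 7.8. All 12 fibroblast genes were (adjusted p = 0.00014; adjusted p = 0.36 with an estimated correlation), with Mfap5 at 7.62, Col15a1 at 3.87, Twist1 at 3.8 and Twist2 at a ratio of 91.8 (16.4 to 3640). Of 18 collagen and matrix genes 17 were higher and Fn1 (-1.95) lower (adjusted p = 2e-07; adjusted p = 0.42 with an estimated correlation). Of 17 mitosis genes 9 were higher, 7 adjusted over the list alone, with Mki67 at 2.73 (adjusted p = 0.027; adjusted p = 0.63 with an estimated correlation). All members were lower in the lists of hepatocyte (14 genes, Ttr -8.49, Fgg -8.89, Ahsg -9.26, Apoa2 -8.55; adjusted p = 8e-14; adjusted p = 0.3 with an estimated correlation) and urea cycle genes (10, adjusted p = 2e-07; adjusted p = 0.3 with an estimated correlation). So were all of the cholesterol synthesis genes (17, Sc5d -5.0, Insig1 -4.95, Fdft1 -4.12, Hmgcs1 -3.95; adjusted p = 4.2e-10; adjusted p = 0.36 with an estimated correlation). The same held for cytochrome P450 (12, adjusted p = 2.8e-05) and oxidative phosphorylation genes (16, adjusted p = 7.9e-07), each with adjusted p = 0.47 with an estimated correlation. Of 14 interferon-stimulated genes 11 were lower, 12 adjusted over the list alone, including Irf7 (-3.47), Bst2 (-3.7), Usp18 (-3.41) and Rtp4 (-2.65; adjusted p = 9e-06; adjusted p = 0.36 with an estimated correlation). Of 7 erythroid genes 6 were lower (adjusted p = 0.009; adjusted p = 0.6 with an estimated correlation).

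The other lists of this comparison were not called. In the epithelial list Krt14 (7.44), Krt5 (3.94) and Esrp1 (3.4) were higher, while the simple epithelium genes Krt8 (-9.91), Krt18 (-9.27) and Cldn3 (-8.66) were lower. Its median was 0.43, its mean -1.37 and its test pointed down (11 members, 3 rose and 5 fell, 4 and 5 adjusted over the list alone; adjusted p = 0.15). Members higher and lower were 4 and 5 of 11 for ErbB receptors and ligands (5 and 5 adjusted over the list alone; adjusted p = 0.51), 7 and 2 of 17 for ERK-responsive genes (0.087) and 7 and 2 of 11 for FOXO targets (0.27). They were 4 and 0 of 16 for DNA replication (1 adjusted over the list alone; 0.24), 1 and 2 of 13 for p53 targets (0.51), 7 and 2 of 12 for proteases (8 and 2 adjusted over the list alone; 0.069) and 4 and 1 of 10 for contractile genes (0.33). Glycolysis had 1 and 7 of 15 (0.054), Wnt 0 and 1 of 7 (median -0.1, mean -0.46, test up, 0.85), MHC class II 0 and 6 of 7 (0.054) and oncofetal genes 0 and 6 of 10 (0.11). Muscle fibre genes had 12 and 0 of 14 (14 adjusted over the list alone; 0.086), myogenic precursors 3 and 0 of 3 (0.33), endothelium 0 and 5 of 10 (0.091) and macrophage 0 and 5 of 14 (4 adjusted over the list alone; 0.088). Neutrophil genes had 0 of 5 in either direction (0.32), T and NK cells 0 and 3 of 7 (0.086), B and plasma cells 1 and 1 of 5 (0.31), cholangiocyte 1 and 2 of 6 (0.35), intestinal epithelium 0 and 2 of 3 (0.16) and adipocyte 3 and 1 of 6 (0.63). With library size alone the medians of p53 targets (-0.2 to 0.78), Wnt (-0.1 to 0.9) and macrophage genes (-0.67 to 0.31) changed sign. In all, 9239 of 16557 genes were past the threshold, 4993 higher and 4246 lower in sarcoma, with 4562 and 3642 by 2-fold or more. The share of higher calls was 54% with TMM scaling and 80.2% with library size alone (8569 higher, 2112 lower), with the median of all genes moving from 0.196 to 1.16. With the mouse as a block, on only the 2 mice that gave both tumours, the count was 3847.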

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

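The tests on a library mix-up at 1 passage, on oral epithelium, on epidermis, on carry-over, on nerve, on central glia and on mature myelin were chosen only after the result was seen. The test on exchanged labels was written before, as were first forms, on partly other genes, of those on nerve and central glia.

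Nrg1 of embryos 1 and 3 went against their genotype labels at both passages. A mix-up of libraries at 1 passage is argued against, since the lowest embryo 1 value was 84.1 times the highest of embryos 5 and 8, and the highest embryo 3 value was 0.015 of the lowest of embryos 7 and 10. An exchange of the labels of embryos 1 and 3 was tested on 100 genes that separate embryos 7 and 10 from embryos 5 and 8, where embryo 1 scored 0.89 and 1.02 and embryo 3 scored 0.88 and 0.76. The smaller of the differences was 0.0057, below the SD of 0.17 among heterozygous scores, so exchanged and correct labels cannot be told apart by these genes, on which heterozygous embryos scored 0.47 to 0.86. The exchange may still be the source, a wrong genotyping of both embryos is open as well, and the biological explanation, a genotype with unusual Nrg1 expression, was not tested.

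Keratins of stratified epithelium were among the most abundant transcripts of all muscle libraries. Carry-over from other libraries of the series is argued against, as the highest Krt13 value elsewhere was 0.0107 of the lowest in muscle. Hairy skin epidermis stays open. Krt1, Krt2, Krt77 and Flg2 to Lor in muscle reached 0.00137 of the lowest sarcoma ratio. Krt2, Krt77 and Flg2 were known as high in sarcoma, so neither this nor Krt1 to Krt10 (0.53, too close) can decide. Oral or another soft stratified epithelium in the muscle samples stays open: 8 of the 10 genes of its list were at least 10 times higher in every muscle library than in any other tissue, but the list was made after Krt13, Krt4 and Krt76 had been seen and cannot support it. No biological explanation was tested, since the design gives no group that separates it.

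Schwann cell genes were high in all sarcoma libraries. Normal myelinated nerve is argued against, because the highest ratio of Mbp to Sox10 in a sarcoma (0.3) was 0.0449 of the lowest in muscle (6.67). Brain tissue with mature myelin is argued against by Mobp relative to Sox10, whose highest sarcoma ratio was 9.21e-05 of the lowest brain ratio. Central glia are argued against by Olig2 plus Mog relative to Sox10 (0.00792 of the lowest brain ratio), although the first form of this test had left them open, and glia that make neither gene were not tested. Non-myelinating Schwann cells of the host were not tested either, and a state of the tumour cells themselves is a hypothesis, since no sorted tumour cells were used here.

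Of 39 groups and measures of 4 to 10 samples examined for a sample far from the others, 7 were found, where chance gives about 1 in 20. Cd74 was at 1430 CPM in the lung of M00238, with the next lung at 449. In muscle, Nrg1 was at 1.3 CPM in M00246 (next 26.4), Erbb4 at 6.09 CPM in M00246 (next 3.11) and Erbb3 at 21.8 CPM in M00237 (next 17.3). Mitochondrial transcripts took 13.4% of the sarcoma of M00236 (next mouse 8.34%, while the T1 library of M00245 alone had 8.41%). In spleen, M00245 had Erbb3 at 3.25 CPM (next 1.54) and Erbb4 at 0.325 CPM (next 0).

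In fibroblasts, the homozygous effect on 6 gene lists differed between passages by a test of the interaction with camera. The lists were macrophage (median log2 difference 0.88, adjusted p = 2.3e-06), interferon-stimulated (1.17, adjusted p = 2.3e-06), p53 targets (-0.77, adjusted p = 2.3e-06), DNA replication (0.39, adjusted p = 8.9e-06), contractile (-0.32, adjusted p = 0.00035) and collagen and matrix genes (0.26, adjusted p = 0.049). With an estimated correlation the adjusted p were 0.42 to 0.45, and without embryo 10 no list was called. In samples outside the comparisons, Erbb4 was at 27 and 49.2 CPM in the 2 brain libraries and Cd74 at 1650 and 1750 CPM in the 2 of the intestine tumour, against at most 6.09 and 1430 in normal liver, lung, spleen and muscle.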

How the results depend on the processing

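The settings with library size alone, without embryos 1 and 3, without the later library of embryo 8, by batch, without mouse M00246 or M00247 and gene lists without embryo 10 were chosen after seeing the data. Over 6635 values of 271 genes named per comparison, 6260 kept their direction and their side of the threshold, 276 lost their call, 62 gained one and 37 changed direction. Of the genes of the naming rule past the threshold, 0 of 55 for sarcoma against muscle and 0 of 32 for sarcoma against 4 tissues lost their call under any setting that gave them a value. For sarcoma against liver tumour 3 of 41 did, Cd74, Krt2 and, with library size alone, Nrg1, for passage 23 of 24 and for the livers 54 of 54. In the livers the block, on 2 mice, ended 53 calls, the second batch 36 and leaving out the tumour of M00248, M00236 or M00249 ended 13, 6 or 3. Where no construction of the setting is named, the cause was not tested. Low counts limit Erbb3, Erbb4 and Cd74 in fibroblasts and Erbb2 in liver.

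Counts of genes past the threshold moved by over 1.5 times as follows. Homozygous against negative at passage 1 (0) gave 9 with DESeq2, 30 with no filter, 2 without embryos 1 and 3 and 0 to 890 leaving out 1 embryo. At passage 3 it gave 1 without embryos 1 and 3. Heterozygous against negative gave 3 at passage 1 and 1 at passage 3 without embryos 1 and 3, 1 with DESeq2 at passage 3, and 0 to 1 at passage 1 leaving out 1 embryo. Homozygous against heterozygous gave 1 with DESeq2 at each passage and 0 to 147 at passage 1 leaving out 1 embryo. The interaction gave 1 without embryos 1 and 3 and 0 to 1 leaving out 1 embryo. The single genes without embryo 1, or without embryos 1 and 3, were mt-Atp6 or Nrg1, the latter with Gm20760 and mt-Atp6 where 3 were called, and Arcn1 without embryo 4, all chosen after their values were seen. Passage (340) gave 581 with DESeq2, 515 with no filter, 142 without the later library of embryo 8, 4 without embryos 1 and 3 and 24 to 779 leaving out 1 embryo. Liver tumour against normal liver (1406) gave 860 to 1919 leaving out 1 library, 2289 in the first batch, whose 1 tumour (M00236) is assumed to vary like the normal livers, and 164 in the second, with 2 tumours. With the mouse as a block it gave 0, with 904 at an unadjusted p below 0.05, and sarcoma against liver tumour gave 3847 with the block. Sarcoma against 4 tissues (1174) gave 2114 with library size alone. The block gave 449 for passage, 0 for the interaction, 8350 for sarcoma against muscle and 845 for sarcoma against 4 tissues, and beyond the named genes given with those comparisons it changed no other call.

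List calls fell to 0 with an estimated correlation in every comparison that had any: from 8, 3, 4 and 3 in the genotype comparisons, 9 for passage, 6 for the interaction, 15 for sarcoma against muscle, 17 for the livers and 11 for sarcoma against liver tumour. Without embryo 10 they went from 0 to 2 (homozygous against negative, passage 3), 0 to 3 (heterozygous against negative, passage 3), 4 to 1 (homozygous against heterozygous, passage 1) and 6 to 0 (interaction). Without embryos 1 and 3 they went from 0 to 3 (homozygous against negative, passage 3) and from 3 to 8 (homozygous against heterozygous, passage 3). With the block they were 8, 19, 16 and 16 for passage, sarcoma against muscle, the livers and sarcoma against liver tumour.

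Of the values that changed direction, those of Dusp5 and Krt5 had been past the threshold and the others had not. Leaving out 1 embryo gave these ranges of log2 fold change. For Erbb2, homozygous vs negative, passage 1 it was -0.17 to 0.23, and for Erbb2, homozygous vs negative, passage 3 it was -0.07 to 0.28. For Nrg1, heterozygous vs negative, passage 1 it was -0.55 to 5.44, for Erbb2, heterozygous vs negative, passage 1 it was -0.13 to 0.17, and for Egfr, heterozygous vs negative, passage 1 it was -0.15 to 0.25. For Nrg1, heterozygous vs negative, passage 3 it was -0.04 to 6.12 and for Erbb2, heterozygous vs negative, passage 3 it was -0.06 to 0.29. For Nrg1, homozygous vs heterozygous, passage 1 it was -0.02 to 1.31, for Erbb2, homozygous vs heterozygous, passage 1 it was -0.24 to 0.21, for Nrg1, homozygous vs heterozygous, passage 3 it was -0.25 to 0.97, and for Erbb2, homozygous vs heterozygous, passage 3 it was -0.17 to 0.1. Without embryos 1 and 3, Egfr, homozygous vs negative, passage 3 gave 0.02 and Erbb2, homozygous vs heterozygous, passage 3 gave 0.02. The Y-linked covariate gave -0.12 for Nrg1 and 0.03 for Erbb2 in that last comparison. Without the later library of embryo 8 at passage 3, Erbb2 gave -0.07 for homozygous and -0.06 for heterozygous against negative, Nrg1 gave -0.05 for heterozygous against negative, and Nrg1, genotype by passage interaction, homozygous vs negative gave -0.43. With library size alone Nrg1, heterozygous vs negative, passage 1 gave -0.01, Nrg1, sarcoma vs muscle 0.63 and Egfr, sarcoma vs muscle 0.67. Nrg1, sarcoma vs muscle gave 0.07 in the second batch and Erbb2, sarcoma vs muscle -0.12 in the first. In the first batch, with its 1 tumour, Nrg1, liver tumour vs normal liver gave -0.32, Dusp5, liver tumour vs normal liver -0.65 and Krt5, liver tumour vs normal liver -0.15.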

Other observations

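The intestine tumour of mouse M00247 had 2 libraries, no replicate mouse and no test. Rgs13, a signalling regulator known from germinal centre B cells, was at 129 CPM over both libraries, 52.96 times the highest other library on the scale of CPM + 1. The transcription factor Mef2b was at 142 CPM (ratio 13.8) and Gcsam at 125 (10.6). The other genes by the same rule were Havcr1 (61.9 CPM), the BMP antagonist Grem1 (126), Mmp10 (11.8), Ly6k (89.4), Ccr10 (19.1) and Gpat2 (26.6), with ratios of 10.2 to 12.9. Mmp10 was at 25.2 CPM in 1 library and 0 in the other. The mean log2(CPM + 1) of B and plasma cell genes was 7.01 and 6.73, within the 5.53 to 7.25 of the 6 spleens. T and NK cell genes were at 4.11 and 4.99, against 2.77 to 4.47 in spleen. Genes of intestinal epithelium were at 0.288 and 0.275, and Cdx2, a factor of intestinal epithelium, was at 0 CPM.

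Mouse M00247 also had high S100a8, a neutrophil gene, at 8894 CPM in spleen, 2899 in lung and 1584 in liver. Mouse M00246 had the lowest Nrg1 of its group in 4 tissues. It was at 0.675 CPM in liver against 27.6 to 83.3 in the others, 1.3 in muscle against 26.4 to 38.5, 2.34 in spleen against 8.16 to 26.9, and 5.37 in lung against 8.93 to 111. Its genotype was not tested. Y-linked genes were unequal between tumour libraries, chosen after their values were seen. Ddx3y was at 22.0 CPM in the sarcoma library T2 of M00245 against 132 in T1, and Uty at 3.14 against 38.0. In the liver tumours of M00249, M00236 and M00248 Ddx3y was at 28.2, 43.4 and 85.4 CPM and Uty at 4.94, 3.73 and 6.74. In fibroblasts, Y-linked Ddx3y marked embryos 1, 2, 3 and 7 and Xist the other 5, so sex was not balanced over the labelled genotypes.

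Counts of genes were also taken for other splits of the same libraries, planned before the counts were seen. For sarcoma against muscle 1 of 100 splits was as large as the real 9541 (highest other 1). It was 1 of 84 for sarcoma against liver tumour (9239, highest other 2) and 1 of 100 for sarcoma against 4 tissues (1174, highest other 0). Every other split mixes tissues, so these counts show only that tissues differ. For the livers 1 of 100 splits was as large (real 1406), but the mouse block (0 genes, only 2 mice) cannot decide. The highest other (1355) set the normal liver of M00247 with the tumours of M00248 and M00249, which points to structure in the samples. Only the M00247 liver was female by Xist (125 CPM). For passage 1 of 100 splits was as large (340, highest other 1). Among splits that part every embryo pair 2 of 100 were, and the highest other called 487 genes with only the pair of embryo 10 exchanged.

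The 6 genotype comparisons and the interaction allow only 10 splits each, too few for a share under 0.05, with 10 of 10 as large as the real count of 0 in each. The highest other was 0 in 5 of them, 1 for homozygous against heterozygous at passage 3, and 1361 for homozygous against heterozygous at passage 1. That split set embryos 4, 6 and 7 against embryos 2, 3 and 10 and points to a structure of the samples other than the labelled genotype, the same 3 embryos being those with few macrophage and interferon transcripts.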
